A study of Mus musculus with 8 samples.

How the data were processed

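Total RNA of 8 hepatocyte cultures, 4 from p16 wild type and 4 from p16 knockout mice, was biotin-labelled and hybridised to Affymetrix whole-transcript gene arrays. The deposited table holds log2 expression values with 41345 rows and 8 columns, each of which was tied to its sample by name. Per the submitters' processing notes the authors used RMA through the oligo package; their versions are not given in the sources used here. RMA corrects the background of each array, forces the arrays to 1 distribution by quantile normalization and summarises the probes of a row, so a change shared by all genes would be removed and changes of dim genes are compressed. The deposited values were used as given, without another background correction. Arrays have no read depth; the lower quartile of the values ran from 2.55 to 2.68 and the upper from 5.63 to 5.76 over the arrays, and precision is set by the 4 arrays per group.

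Rows were named from the platform's annotation table. Of the rows, 23521 had 1 gene symbol, 1814 had several and 16010 had none; only the former were named, and 23328 of them matched a RefSeq table (GRCm38.p6) by gene identifier, with 0 symbols changed. They cover 22180 genes, 1082 of them with several rows, for which the row with the highest mean over all arrays was kept. Members of a gene list without a row of their own were not analysed here. Genes were tested if their mean over the 8 arrays lay above the 40th percentile of all row means (3.32 on the log2 scale), which left 15380.

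Knockout and wild type arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, 6 residual and 5.05 prior degrees of freedom), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Changes are knockout minus wild type on the log2 scale, errors of changes are limma's moderated standard errors, and p-values are two-sided. Gene lists for metabolism, stress, signalling, cell cycle and the cell types a liver preparation can hold were written from textbook knowledge before the data were examined, 42 in number, and genes within 10 Mb of Cdkn2a were added as a list. Lists with at least 5 tested genes were tested with camera at a preset correlation between genes of 0.01, adjusted over the 42 lists that qualified, since the list of Y-linked genes and Xist fell short. The test was repeated with the correlation estimated from the residuals, and with fry, which tests whether a list's own genes move one way on balance. With the preset correlation 26 lists passed (18 upward, 8 downward), with an estimated one 5 did, namely sinusoidal endothelial cells, Kupffer cells, xenobiotic metabolism, inflammation and male-biased liver genes, and with fry 31 did. Cdkn2a and list means were also compared by an exact permutation test over the 70 arrangements of the samples, whose smallest p is 0.0286.

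The genes to be named were also fixed before the data were examined. They are Cdkn2a and Cdkn2b; the 8 largest rises and 8 largest falls among genes past the threshold without overlap between the groups, leaving out predicted genes, clones and small RNAs; the 4 members of smallest p from each of the 6 lists on fasting metabolism and the cell cycle (PPARa targets, fatty acid oxidation, ketone bodies, gluconeogenesis, oxidative phosphorylation, E2F targets); the 3 of smallest p in the list's direction from each other list that passed; and the 2 of highest mean from each other cell type list. This gave 105 names, some under several parts of the rule. Names outside it are said to be chosen after their values were seen.

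The fitting procedure was tested on simulated data drawn from the real means and spreads of the 15380 genes for this comparison. Of genes changed by 0.5, 1 and 2 on the log2 scale, 38.8%, 92.5% and 100% were called, 8.33% of calls fell on unchanged genes, and with no gene changed 0 were called. A simulated list shifted by 0.3 was the 1 list called. The simulated genes varied independently of each other, so this does not show how often lists of correlated genes are called wrongly. Alternatives set before the data were examined were another filter on dim genes, other rules for genes with several rows, cyclic loess, quantile normalization or median centring on top of the deposited values, other variance models, array weights, the replicate number as a block, other thresholds, other windows around Cdkn2a and leaving out each array in turn. Calculations outside R were done in Python 3.11.15.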

Results

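Gene expression was measured in primary mouse hepatocytes, the parenchymal cells of the liver, taken from p16 knockout mice and their p16 wild type littermates. p16 is the product of Cdkn2a that inhibits the cyclin-dependent kinases CDK4 and CDK6 and so restrains E2F-driven cell cycle entry. The cells were freed from the liver by perfusion with collagenase and left to attach overnight in medium with 10% fetal bovine serum, 100 nM insulin and 25 nM dexamethasone. At 16 h they were moved to medium with 1 mM glucose and 0.1% albumin for 8 h, and RNA was taken at 24 h. Each group had 4 samples and each sample 1 array. The labels call the samples biological replicates but do not say whether each came from its own animal and preparation, so p-values measure the spread between these samples. The comparison asks which genes differ between p16 knockout and wild type hepatocytes after a period in low-glucose medium.

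The 8 arrays had closely similar distributions, with medians of 3.76 to 3.88 on the log2 scale. Correlations between arrays across all genes tested were 0.985 to 0.993 within a group and 0.973 to 0.983 between groups. The leading principal component, with 47.5% of the variance, placed all 4 knockout arrays on one side of all 4 wild type arrays. The next component held 17.9% and set knockout replicate 4 apart from the other arrays, at -25.2 against -8.91 to 14.6. The precision of every value below is limited by the 4 arrays per group.

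The targeted gene was examined ahead of the others. Cdkn2a was measured at 4.53 ± 0.28 (SD, n = 4) in wild type and 4.53 ± 0.31 in knockout hepatocytes, a change of 0.0040 on the log2 scale with a 95% interval of -0.37 to 0.38 (two-sided exact permutation p = 1). The 8 arrays ranged from 4.16 to 4.91 and the groups overlapped. The array holds 1 row for Cdkn2a, a gene that encodes both p16 and ARF. Which transcripts its probes measure, and which part of the gene is deleted, are not given in the sources used here. A probe set outside the deleted part could not check the genotype, and where this one lies is not known. Whether a value of 4.53 stands above background in wild type cells was not tested. The row is therefore not taken to bear out or contradict the labels. Cdkn2b, the adjacent gene for the related inhibitor p15, was at 5.62 ± 0.20 in wild type and 5.66 ± 0.08 in knockout cells (exact permutation p = 0.714). The Y-linked genes Eif2s3y, Kdm5d and Uty differed between the groups by 0.32, -0.22 and -0.28 and Xist by 0.10, with no call in the test across all genes.

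**Figure D1:**
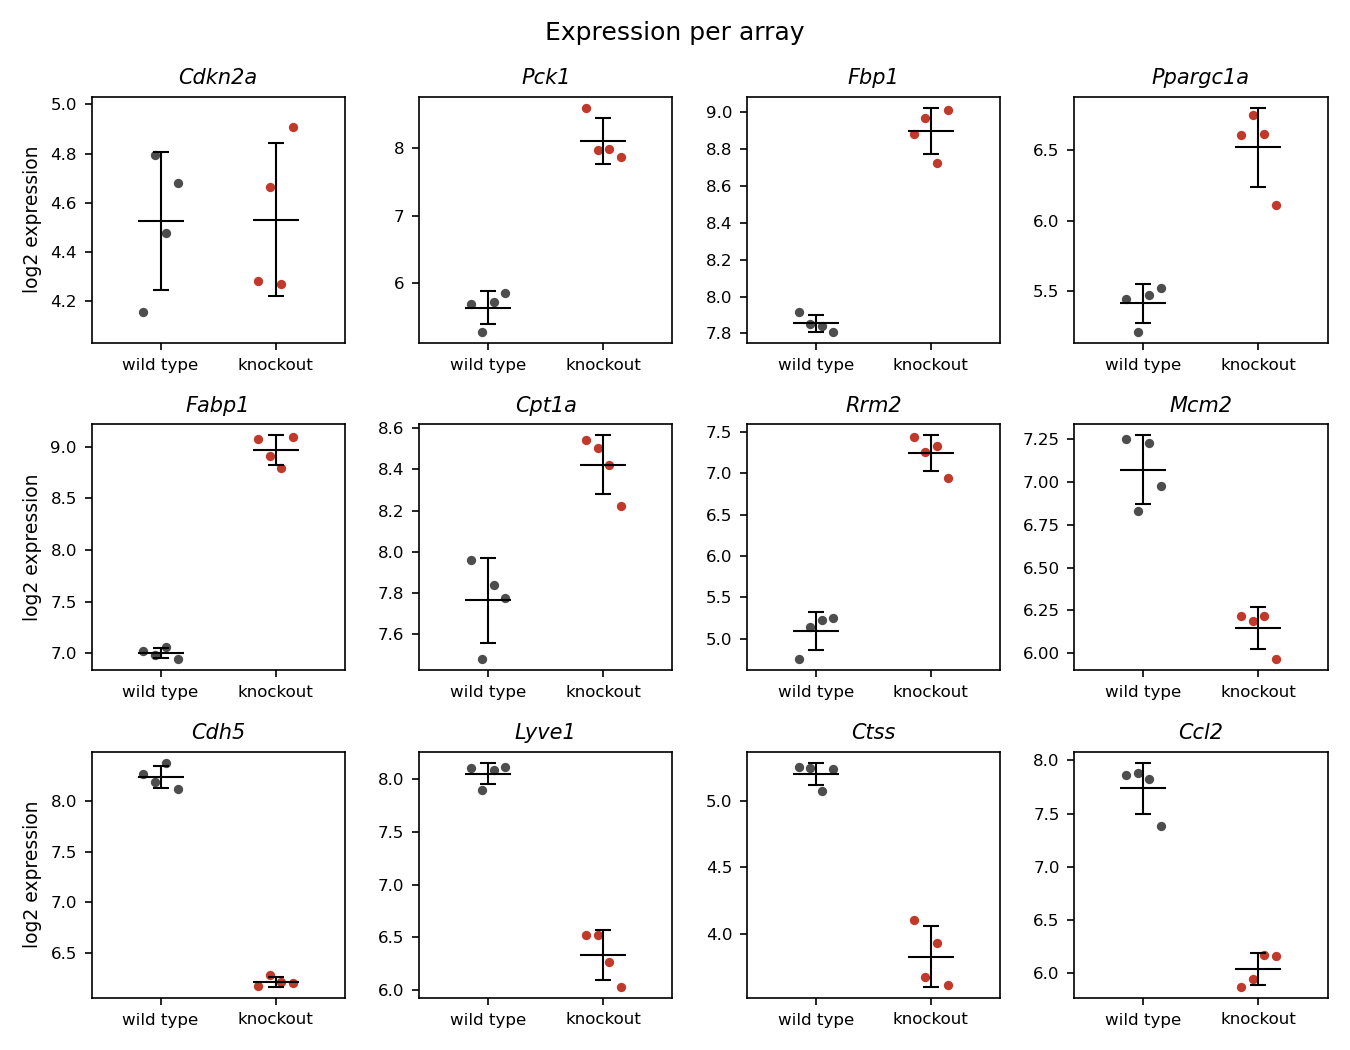
Log2 expression of 12 genes on each of the 8 arrays (points), with the mean and SD of the 4 arrays per group (bar and whiskers); vertical axes differ between panels and do not start at 0. Cdkn2a overlaps between the groups at a mean of 4.53 in both, whereas Pck1 has a mean of 5.64 in wild type and 8.10 in knockout arrays and Cdh5 means of 8.24 and 6.21.

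Of 15380 genes tested, 2119 differed between knockout and wild type hepatocytes, 1080 higher and 1039 lower in the knockout (limma, adjusted p under 0.05). The change reached 2-fold for 164 of the higher and 109 of the lower genes. Fezf1, a transcription factor known from forebrain development, rose most, from 4.73 ± 0.09 to 8.62 ± 0.37 (SD, n = 4), which is 14.8-fold (log2 change 3.89, SE 0.16, adjusted p = 4.39e-07). It was followed by Hamp, which encodes the iron hormone hepcidin, with a log2 change of 2.91 (SE 0.26), by the urea cycle enzyme Arg1 at 2.69 (SE 0.18), by Mat1a, the hepatocyte form of methionine adenosyltransferase, at 2.51 (SE 0.15), and by the steroid dehydrogenase Hsd3b5 at 2.51 (SE 0.37), whose wild type mean of 3.11 lies below the 3.32 used to filter dim genes, so that its size and rank are uncertain. Pck1 (2.47), Rasgef1b (2.45) and the tyrosine catabolic enzyme Hgd (2.34) completed the 8 largest rises. The noncoding RNA Wincr1 fell by 3.15 (SE 0.21), the largest fall among the genes tested, and Dcn, which encodes the matrix proteoglycan decorin, fell by 2.13 (SE 0.16). Abcc4 (-2.09), Esm1 (-2.09), Slc4a11 (-2.07), the endothelial cadherin gene Cdh5 (-2.03), Cyp4b1 (-1.99) and Sox4 (-1.93) followed. Groups did not overlap for 1996 of the 2119 genes. Over all genes tested 3114, or 20.2%, had groups that did not overlap, where chance gives 2.86%. Of the changed genes 90 have predicted or clone names and were only counted. At an unadjusted p under 0.05 the count was 4137, and with a required change of 1.5-fold it was 895.

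**Figure D2:**
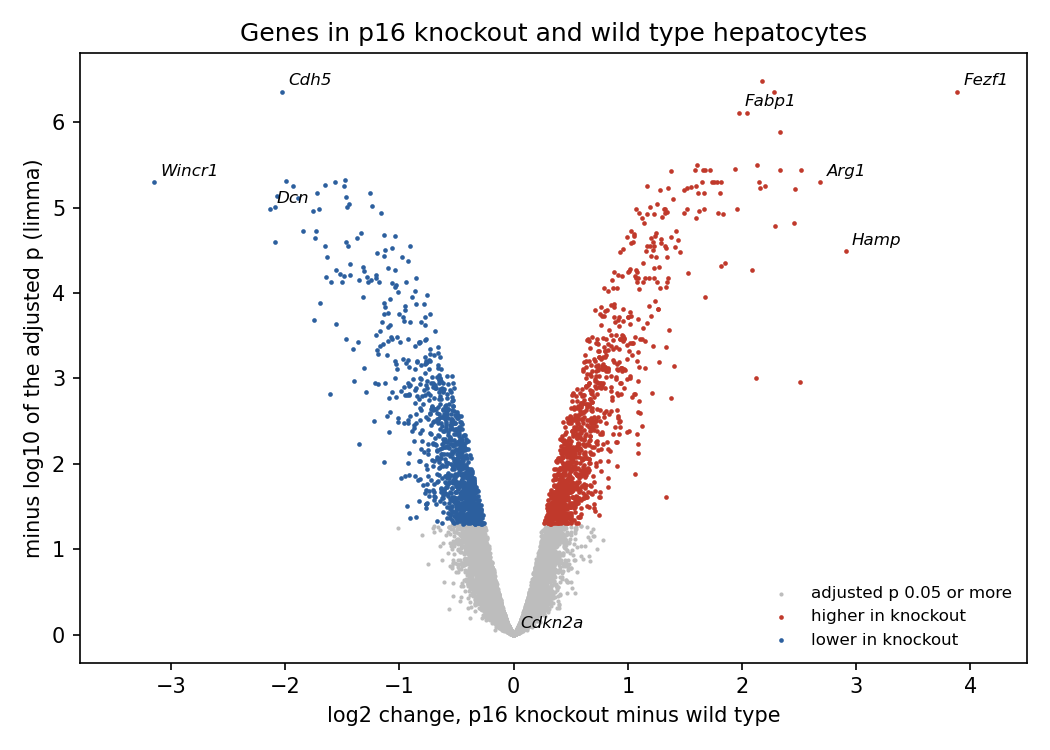
Each point is 1 of the 15380 genes tested, with the log2 change (knockout minus wild type, 4 arrays each) on the horizontal and minus log10 of limma's adjusted p on the vertical axis; red and blue mark the 1080 higher and 1039 lower genes. Fezf1 lies farthest to the right at 3.89 and Wincr1 farthest to the left at -3.15, and Cdkn2a lies at the bottom centre.

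Genes of gluconeogenesis, the synthesis of glucose from lactate, amino acids and glycerol, were higher in the knockout. Of 36 tested members 17 rose, none fell and 19 did not pass the test; adjusted over the list alone, 18 rose. Pck1, the enzyme that makes phosphoenolpyruvate from oxaloacetate, rose 5.53-fold (log2 change 2.47, SE 0.17, adjusted p = 6.12e-06). The glucose 6-phosphate transporter Slc37a4 rose by 1.20 (SE 0.11), Fbp1, which encodes fructose 1,6-bisphosphatase, by 1.04 (SE 0.09) and Pcx, which encodes pyruvate carboxylase, by 0.95 (SE 0.09). The coactivator Ppargc1a, which induces this programme during fasting, rose by 1.11 (SE 0.14). The list shifted upward against all other genes (camera, adjusted p = 5.00e-11), and with an estimated correlation between its genes that call was lost (adjusted p = 0.177). In the same arrays genes typical of mature hepatocytes were also higher: 18 of 31 tested members rose and none fell (22 and none adjusted over the list alone), among them Arg1, the urea cycle gene Cps1 (1.32, SE 0.10) and the tyrosine catabolic gene Hpd (1.84, SE 0.14). That list passed camera at an adjusted p of 1.31e-15, and its adjusted p was 0.0623 with an estimated correlation. The gluconeogenesis and mature hepatocyte lists share 3 tested genes. On the same arrays the list means of endothelial and macrophage markers were lower by 0.83 and 0.59.

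Targets of PPARa, the nuclear receptor that switches on fat use in the fasted liver, moved both ways. Of 58 tested members 17 rose and 6 fell, with 19 and 6 adjusted over the list alone. The fatty acid binding protein gene Fabp1 rose 3.92-fold (log2 change 1.97, SE 0.09, adjusted p = 7.77e-07), the glycogen synthase gene Gys2 by 1.75 (SE 0.11) and the lipid droplet gene Cidec by 1.53 (SE 0.15). Cyp4a14, a fatty acid hydroxylase and a classical target of the receptor, fell by 0.91 (SE 0.08). The list passed camera upward at an adjusted p of 0.00187, against an adjusted p of 0.416 with an estimated correlation. Knockout replicate 4 had a list mean of -0.03, beside the highest wild type value of -0.04, while the other knockout arrays had 0.09 to 0.17. Mature hepatocyte genes were higher on the same arrays, by a list mean of 0.58, and endothelial markers lower by 0.83.

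On the same arrays, with mature hepatocyte genes higher by a list mean of 0.58 and endothelial and macrophage markers lower by 0.83 and 0.59, 6 of 33 tested members of mitochondrial fatty acid oxidation rose and 2 fell, with 8 and 2 adjusted over the list alone. Acsm1, a medium-chain acyl-CoA synthetase gene, rose by 1.23 (SE 0.12), Cpt1a, whose enzyme controls the entry of fatty acids into mitochondria, by 0.66 (SE 0.12) and the thiolase gene Acaa2 by 0.63 (SE 0.10), while the acyl-CoA thioesterase gene Acot2 fell by 1.11 (SE 0.15). The other fall, named after its value was seen, was that of Acsl4 (-0.46). The list passed camera at an adjusted p of 0.0439, had an adjusted p of 0.562 with an estimated correlation, and shares 17 tested genes with the PPARa list. Leaving out wild type replicate 2 or 4 or knockout replicate 1 or 3 ended this call, with adjusted p-values of 0.164, 0.0657, 0.0924 and 0.0648. Of 7 tested genes of ketone body metabolism 1 rose, and adjusted over the list alone 6 rose and 1 fell. The riser was Aacs, which activates acetoacetate in the cytosol, at 0.28 (SE 0.08, adjusted p = 0.0471). Its call ended under 10 alternatives, 7 of which leave out 1 array, with adjusted p-values of 0.0643 to 0.134. Bdh1 had a change of 0.38 (SE 0.12, adjusted p = 0.0537), Bdh2 one of 0.34 (SE 0.11, adjusted p = 0.0601) and the monocarboxylate transporter gene Slc16a1 one of -0.24 (SE 0.08, adjusted p = 0.0721). Camera gave this list an upward shift at an adjusted p of 0.0148, and the adjusted p was 0.276 with an estimated correlation.

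On these arrays, with the same shifts of hepatocyte (0.58), endothelial (-0.83) and macrophage (-0.59) list means, 3 of 70 tested genes of oxidative phosphorylation rose and none fell, and adjusted over the list alone 2 rose. The 3 were the complex I genes Ndufa8 (0.48, SE 0.08), Ndufb9 (0.43, SE 0.08) and Ndufs3 (0.31, SE 0.08), whose call ended under 11 alternatives with adjusted p-values up to 0.0824. The Ndufa8 call ended with the mean of a gene's rows (0.32, adjusted p = 0.0681), and Sdha of complex II had a change of 0.27 (SE 0.09, adjusted p = 0.0755). The list as a whole was shifted upward by a mean of 0.10 (camera, adjusted p = 8.45e-04), with an adjusted p of 0.398 under an estimated correlation, and the groups overlapped, with knockout replicate 2 (-0.02) among the wild type arrays (-0.11 to -0.0042). Of 30 tested peroxisomal genes 8 rose and none fell (9 and 2 adjusted over the list alone), led by the sterol carrier gene Scp2 (1.23, SE 0.10), Pipox (1.30, SE 0.10) and Phyh (0.76, SE 0.09), with a camera adjusted p of 3.49e-04 and an adjusted p of 0.416 with an estimated correlation. The peroxisome and PPARa lists have members in common. Of 29 regulators around AMPK and the sirtuins, the enzymes that sense energy charge and NAD, 6 rose and none fell, the same counts as adjusted over the list alone. They included Ppargc1a, the AMPK subunit gene Prkab2 (0.92, SE 0.14) and Sesn1 (0.90, SE 0.17). Camera's adjusted p for this list was 0.0278 and the adjusted p was 0.496 with an estimated correlation. The call also ended without knockout replicate 1 (0.0612) or 3 (0.0846), with the 60th percentile filter (0.0881) and with fry (0.134). The list mean of knockout replicate 4 (-0.11) lay among those of the wild type arrays (-0.14 to -0.0056), while the other knockout arrays had 0.11 to 0.16.

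Other metabolic groups of the liver were higher as well, on arrays whose mature hepatocyte list mean was higher by 0.58 and whose endothelial list mean was lower by 0.83. Of 33 tested genes of xenobiotic metabolism 20 rose and none fell (20 and 1 adjusted over the list alone), including Cyp1a2 (1.56, SE 0.11), Ugt2b1 (1.49, SE 0.10) and Sult1a1 (1.17, SE 0.08), and the list passed both camera (adjusted p = 2.72e-15) and camera with an estimated correlation (adjusted p = 0.0240). Of 19 genes of bile acid metabolism 10 rose and 2 fell (13 and 3 adjusted over the list alone). The uptake transporter genes Slco1b2 (1.82, SE 0.12), Slc10a1 (1.67, SE 0.10) and Slco1a1 (1.52, SE 0.10) rose, and the falls were those of the export pump genes Abcc4 and Abcc2 (-0.52), the latter named after its value was seen. The adjusted p of this list was 6.21e-07 and, with an estimated correlation, 0.0574. Of 19 genes of cholesterol biosynthesis 12 rose and none fell (13 and none adjusted over the list alone), among them Tm7sf2 (0.80, SE 0.09), Ebp (0.76, SE 0.11) and Insig1 (0.59, SE 0.10), at an adjusted p of 1.99e-08 and an adjusted p of 0.0718 with an estimated correlation. Of 27 genes of lipogenesis 11 rose and 2 fell (12 and 3 adjusted over the list alone), with rises of the desaturase gene Scd1 (1.19, SE 0.09), Khk (1.02, SE 0.11) and Thrsp (1.00, SE 0.10) and, named after their values were seen, falls of Txnip (-0.61) and Mid1ip1 (-0.45). That list had an adjusted p of 1.85e-04 and one of 0.416 with an estimated correlation. The glycolysis list has members in common with the gluconeogenesis list. Of 21 genes of glycolysis 7 rose and none fell (8 and none adjusted over the list alone), among them the glucose transporter gene Slc2a2 (1.26, SE 0.09), Pfkfb3 (0.82, SE 0.16) and Hk1 (0.57, SE 0.11), with an adjusted p of 1.04e-04 and one of 0.180 with an estimated correlation.

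Markers of the other cells of the liver differed between the groups in the same arrays. Of 28 tested markers of sinusoidal endothelial cells, which line the liver's capillaries, 22 fell and 1 rose, the same counts as adjusted over the list alone. Cdh5 fell 4.07-fold (log2 change -2.03, SE 0.09, adjusted p = 4.39e-07), the hyaluronan receptor gene Lyve1 fell by 1.72 (SE 0.12) and the endoglin gene Eng fell by 1.56 (SE 0.10), while Flt1, named after its value was seen, rose by 0.62. Of 22 markers of Kupffer cells, the resident macrophages, 14 fell and 2 rose (15 and 2 adjusted over the list alone). Ctss fell by 1.37 (SE 0.12), the NADPH oxidase gene Cybb by 1.20 (SE 0.15) and Fcer1g by 0.91 (SE 0.11), and the risers, named after their values were seen, were Cd68 (0.58) and H2-Ab1 (0.75). Of 22 markers of stellate cells and fibroblasts 5 fell and 1 rose (7 and 1 adjusted over the list alone), with falls of Dcn, Rgs5 (-1.65, SE 0.11) and Ecm1 (-0.95, SE 0.11) and, named after its value was seen, a rise of Reln (0.99). Mean log2 values of the endothelial, macrophage and stellate lists were lower in the knockout by 0.83, 0.59 and 0.36, in each case with no overlap between the groups (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 samples can give). The endothelial and macrophage lists passed camera at adjusted p-values of 5.00e-17 and 2.19e-07, and both kept the call with an estimated correlation (adjusted p = 0.0197 for each). The stellate list passed at 0.00196 and had an adjusted p of 0.157 with an estimated correlation.

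**Figure D3:**
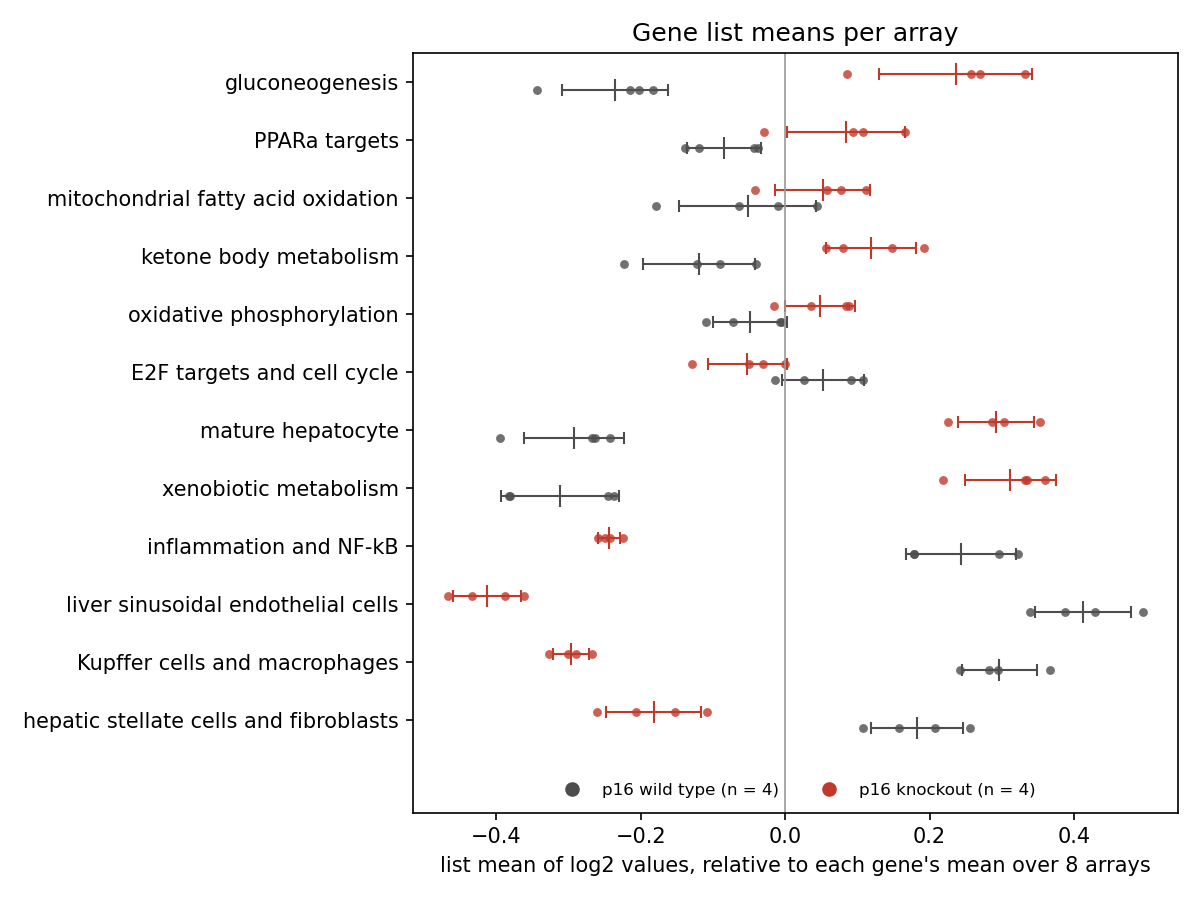
Mean log2 value of 12 gene lists on each array (points), relative to each gene's mean over the 8 arrays, with the mean and SD of the 4 arrays per group (bar and whiskers; wild type grey, knockout red). The mature hepatocyte list is higher and the endothelial list lower on every knockout array than on any wild type array, while the groups overlap for mitochondrial fatty acid oxidation, oxidative phosphorylation and E2F targets.

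Inflammatory genes were lower in the knockout. Of 26 tested members of the list of inflammation and NF-kB, a transcription factor of the inflammatory response, 12 fell and 1 rose (17 and 1 adjusted over the list alone). The chemokine genes Ccl2 and Cxcl1 fell by 1.70 (SE 0.13) and 1.55 (SE 0.15) and Ier3 by 0.98 (SE 0.09), and the riser, named after its value was seen, was Bcl3 (0.67). The list passed camera at an adjusted p of 2.19e-07 and, with an estimated correlation, at an adjusted p of 0.0240. In the same arrays the macrophage and endothelial list means were lower by 0.59 and 0.83. Of 27 genes of the senescence secretome, the factors that senescent cells release, 10 fell and 1 rose (11 and 3 adjusted over the list alone). Beside Ccl2 and Cxcl1, which belong to both lists, Igfbp7 fell by 1.16 (SE 0.09), and the riser, named after its value was seen, was Tnfrsf1a (0.34). Its adjusted p was 0.00942, and 0.180 with an estimated correlation, and 6 of its tested genes stand on the inflammation list too. Of 31 genes of TGF-beta signalling and matrix 5 fell and 3 rose (8 and 3 adjusted over the list alone), with falls of Sparc (-1.25, SE 0.09), Tgfb1 (-1.13, SE 0.12) and Mmp14 (-0.59, SE 0.14) and, named after their values were seen, rises of Lox (1.33), Ccn2 (0.49) and Vim (0.38). The adjusted p of this list was 0.0243, and 0.124 with an estimated correlation. Its call also ended with the 60th percentile filter (0.186) and with an intensity trend, robust or not (0.0558). The Mmp14 call ended without wild type replicate 1 (0.0618) or 3 (0.0562).

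E2F targets and cell cycle genes, the group downstream of the kinases that p16 inhibits, moved in both directions, on arrays whose endothelial, macrophage and stellate list means were lower by 0.83, 0.59 and 0.36. Of 63 tested members 2 rose, 9 fell and 52 did not pass the test, with the same 2 and 9 adjusted over the list alone. Rrm2, the regulatory subunit of ribonucleotide reductase, rose 4.44-fold (log2 change 2.15, SE 0.14, adjusted p = 5.01e-06) and the repressor E2f8 rose by 1.67 (SE 0.18). The replicative helicase genes Mcm2 and Mcm3 fell by 0.92 (SE 0.12) and 0.83 (SE 0.10). The list shifted downward in camera at an adjusted p of 0.0463, which became an adjusted p of 0.416 with an estimated correlation. Leaving out wild type replicate 1 or 3 or knockout replicate 1, 3 or 4 ended the call, with adjusted p-values of 0.105, 0.0591, 0.0687, 0.0662 and 0.0625. Of 25 genes of the cyclin-dependent kinase network 4 fell and none rose, the same as adjusted over the list alone, and that list did not pass camera (adjusted p = 0.184). The 4, named after their values were seen, were Ccnd2 (-1.65), Cdk6 (-1.12), Rbl1 (-0.49) and Tfdp1 (-0.42).

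Genes near Cdkn2a on chromosome 4 were compared with the rest of the genome, since a targeted allele carries its flanking sequence with it. Of 60 tested genes within 10 Mb, 13 changed (11 lower, 2 higher), or 21.7% (95% exact binomial interval 12.1 to 34.2), against 2106 of 15319 genes elsewhere, or 13.7% (odds ratio 1.74, two-sided Fisher's exact test, p = 0.0888). Within 5 Mb the odds ratio was 1.36, from 5 of 28 genes (Fisher's exact test, p = 0.579). Within 10 Mb but without knockout replicate 3 the odds ratio was 2.07 (Fisher's exact test, p = 0.0259), and within 20 Mb it was 1.77, from 29 of 132 genes (p = 0.0105). Tested as a list, Cdkn2a and the 60 genes within 10 Mb did not pass camera (adjusted p = 0.211, and 0.470 with an estimated correlation). Fry, which does not compare them with other genes, found them lower on balance (adjusted p = 0.00761). The 3 tested genes next to Cdkn2a on one side were all lower in the knockout. Mtap, which encodes methylthioadenosine phosphorylase, fell by 0.75 (SE 0.11, adjusted p = 7.80e-04), Wincr1 fell from 6.98 ± 0.37 to 3.83 ± 0.37 (SD, n = 4) and the microRNA gene Mir31 fell by 0.50 (SE 0.13, adjusted p = 0.0288). Mtap and Mir31 were chosen after their values were seen. On the other side Cdkn2b had a change of 0.04 (SE 0.11) and Elavl2 one of -0.07 (SE 0.12), neither past the test. Gene order was taken from a RefSeq table of the assembly GRCm38.p6, and no coordinates are given because the build behind the array's annotation is not given in the sources used here.

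**Figure D4:**
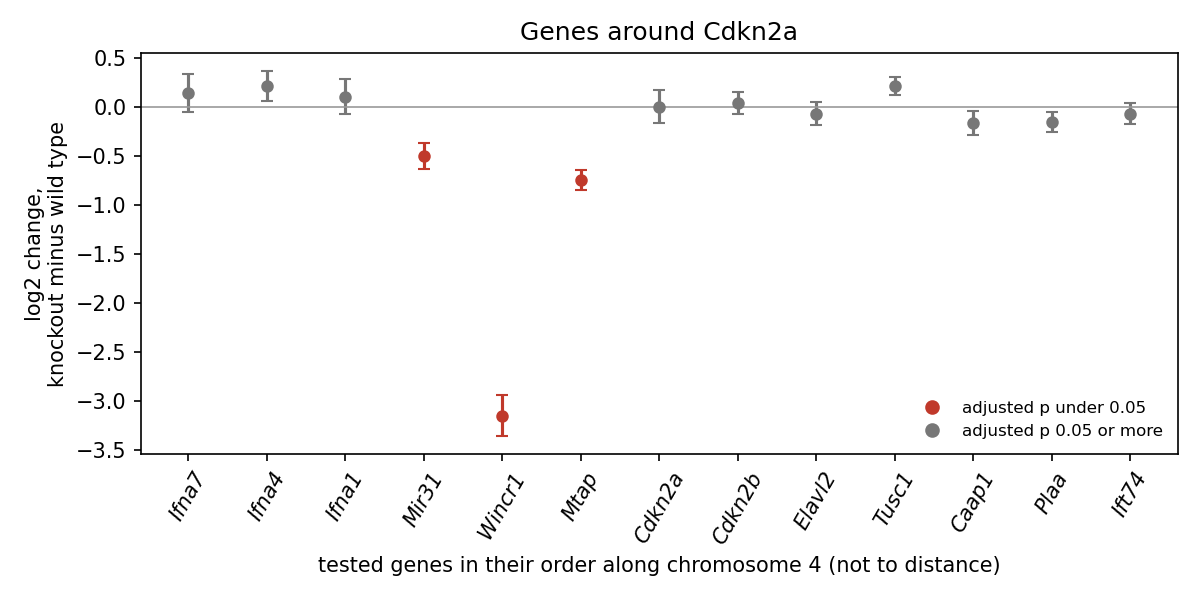
Log2 change (knockout minus wild type, with SE, 4 arrays per group) of 13 tested genes in their order along chromosome 4 around Cdkn2a; the spacing does not show distance. Mir31, Wincr1 and Mtap lie at -0.50, -3.15 and -0.75 with an adjusted p under 0.05, and Cdkn2a at 0.0040.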

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

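No test in this part was chosen after its result was seen. The values examined were those of each named gene, each list mean, the leading and next principal components and each array's mean correlation with its own group. Within each group of 4 arrays they were examined for 1 array set apart from the others, by the ratio of its gap to the whole range. Of 300 such groups 19 passed the critical value, where chance alone flags about 1 in 20, or 15. Knockout replicate 4 was the distant array in 8 of the 19, and 6 of those 8 were list means.

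Knockout replicate 4 had a mean of 0.092 for cholesterol biosynthesis (the other knockout arrays 0.20 to 0.21, relative to each gene's mean over the 8 arrays), of -0.28 for NRF2 targets (-0.08 to -0.06), of -0.12 for TGF-beta and matrix (-0.07 for the other arrays), of -0.10 for the circadian clock (0.15 to 0.18), of 0.16 for male-biased liver genes (0.38 to 0.42) and of 0.0015 for female-biased liver genes (0.27 to 0.29). Among genes it was lowest for Mcm2, at 5.97 against 6.19 to 6.22, and for Cyp1a2, at 8.96 against 9.26 to 9.31. Without this array 2165 genes differed between the groups, of which 1849 were also among the 2119.

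Wild type replicate 4 was lowest for Slc4a11 (8.56, the others 8.96 to 9.03), Gys2 (4.58, the others 4.78 to 4.81), Ccl2 (7.38, the others 7.83 to 7.88) and Igfbp7 (6.61, the others 6.74 to 6.76). Wild type replicate 2 was lowest for Lyve1 (7.90, the others 8.09 to 8.12) and for the mature hepatocyte list mean (-0.40, the others -0.27 to -0.24). Wild type replicate 1 was highest for Slc16a1 (9.67, the others 9.61 to 9.62) and wild type replicate 3 lowest for Ctss (5.08, the others 5.23 to 5.25). Among knockout arrays, replicate 1 was lowest for Igfbp7 (5.39, the others 5.61), and replicate 3 for Rpl6 (4.28, the others 5.02 to 5.16) and Fcer1g (4.37, the others 4.71 to 4.73).

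Rows that carry no gene symbol or several were outside the comparison. Of 8574 such rows bright enough to test, 108 differed between the groups, 70 higher and 38 lower in the knockout.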

How the results depend on the processing

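Every alternative in this part was set before the data were examined. The count of changed genes, 2119, ran from 1610 with arrays centred on their median to 2623 with a robust intensity trend, and from 1448 to 2165 with 1 array left out. It was 895 with a required change of 1.5-fold, 4137 at an unadjusted p and 2950 at an adjusted p under 0.1. The replicate number as a block gave 2215 genes, 1937 of them shared, and 24 lists, and it ended the calls of mitochondrial fatty acid oxidation (adjusted p = 0.0547) and of the growth hormone and IGF axis (0.0514). Deviations of same-numbered arrays correlated at 0.06, 0.02, 0.26 and 0.21, and 4 of 8 arrays correlated best with their own number. These values do not settle whether the numbers pair the samples, and the main comparison uses no block. The count of lists past camera, 26, was 22 to 27 elsewhere, 31 with fry, and 5 with an estimated correlation, where adjusted p was 0.416 for PPARa targets, 0.416 for E2F targets, 0.177 for gluconeogenesis, 0.276 for ketone bodies, 0.562 for fatty acid oxidation and 0.398 for oxidative phosphorylation.

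The fatty acid oxidation call also ended with the 60th percentile filter (adjusted p = 0.118), quantile normalization (0.0574), an intensity trend, robust or not (0.0523), array weights (0.0510) and fry (0.158), and ranged from 0.0105 to 0.164 with 1 array left out. The ketone body call ended with the 60th percentile filter (0.0595). The E2F call ended without a filter (0.123), with quantile normalization (0.0644) and with an intensity trend, robust or not (0.0558), and ranged from 0.0281 to 0.105 with 1 array left out. The odds ratio near Cdkn2a, 1.74, passed the threshold within 20 Mb (1.77) and without knockout replicate 3. It did not pass within 5 Mb (1.36, Fisher's exact test, p = 0.579), and it ranged from 1.27 to 2.07 with 1 array left out. In each case the cause was not tested. Cdkn2a did not pass the test under any setting, with changes from -0.12 to 0.09. Of the 105 named genes, none that passed the test changed sign, and 7 that did not pass, Cdkn2a among them, did under some alternative; 94 kept their side of the threshold under all alternatives that use every array and 97 under all that leave 1 out. Aacs and Ndufs3 lost their calls most often, both close to the threshold. Bdh1, Bdh2, Slc16a1, Sdha, Cdh1, Rpl3 and Rpl6 did not pass in the main setting but passed under some alternatives. Without the filter on dim genes 22180 genes were tested and 1656 called; the cause was not tested.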

Other observations

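Tests described here as chosen after the results were seen are those on the hepatocyte share, on cells other than hepatocytes, on the differentiated state, on gluconeogenic against hepatocyte genes and on E2F targets. The check for a variant under the probes of Wincr1 concerns a gene picked by its fall. The others were set before.

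Several other gene lists also moved. On the same arrays the mature hepatocyte list mean was higher by 0.58 and the endothelial and macrophage list means lower by 0.83 and 0.59. Some genes named here stand on lists above too: Irs2 and Igfbp1 on the gluconeogenesis list and Pfkfb3 on the glycolysis list. The shifts are therefore not all separate from those above. Of 25 tested acute phase genes, which the liver secretes during inflammation, 11 rose and none fell (12 and none adjusted over the list alone), led by Hamp, Orm3 (2.15, SE 0.15) and Crp (1.78, SE 0.11), at a camera adjusted p of 8.07e-07 and an adjusted p of 0.121 with an estimated correlation. Of 19 genes known to be higher in male liver 10 rose and 1 fell, the same as adjusted over the list alone, among them Hsd3b5, Elovl3 (1.95, SE 0.15), Selenbp2 (1.59, SE 0.09) and Slco1a1, with Cyp2u1 (-0.73, named after its value was seen) as the fall. The adjusted p was 4.62e-10, and 0.0460 with an estimated correlation. Of 7 genes higher in female liver 1 rose, Cyp17a1 (2.29, SE 0.19), while Nipal1 had a change of 0.02, and the list did not pass (adjusted p = 0.0656, and 0.331 with an estimated correlation), though it did without wild type replicate 1 (0.0298), without knockout replicate 4 (0.0410) and with fry (0.0117). Of 16 genes of the growth hormone and IGF axis 5 rose and 1 fell (6 and 2 adjusted over the list alone), with rises of Irs2 (1.38, SE 0.22), Igfbp1 (0.77, SE 0.11) and the receptor gene Ghr (0.73, SE 0.11) and, named after its value was seen, a fall of Igfbp3 (-0.53), at adjusted p-values of 0.0248 and, with an estimated correlation, 0.416; the call also ended without knockout replicate 1 (0.0561) and with the replicate block (0.0514). The list mean of knockout replicate 4 (-0.09) lay among those of the wild type arrays (-0.16 to -0.0039). Of 21 hypoxia genes 8 rose and none fell (10 and none adjusted over the list alone), including Adm (1.27, SE 0.17), Pfkfb3 and P4ha2 (0.70, SE 0.12), at 6.23e-07 and, with an estimated correlation, an adjusted p of 0.341. Of 38 genes of autophagy and lysosome 8 rose and 1 fell (9 and 1 adjusted over the list alone), including Atg13 (0.83, SE 0.12), Gabarapl1 (0.66, SE 0.13) and Atp6v0d1 (0.39, SE 0.08), with Sqstm1 (-0.42, named after its value was seen) as the fall, at 0.00187 and, with an estimated correlation, an adjusted p of 0.416. Here too the list mean of knockout replicate 4 (-0.03) lay below the highest wild type value (-0.02). Of 46 cytosolic ribosomal protein genes 1 fell, Rpl32 (-0.31, SE 0.08), and none adjusted over the list alone. The Rpl32 call ended under 9 alternatives, 7 of which leave out 1 array, with adjusted p-values up to 0.0820. Rpl6 (-0.51) and Rpl3 (-0.34) did not pass in the main setting. Rpl6 passed with the 60th percentile filter (adjusted p = 0.0499). Rpl3 passed with its row of largest interquartile range (-0.46, adjusted p = 0.0239), with the mean of its rows (-0.37, adjusted p = 0.0242) and under other alternatives. That list was lower by a mean of 0.12 (adjusted p = 0.00895, and 0.455 with an estimated correlation), and its groups overlapped.

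Other lists did not pass camera in the main setting. NRF2 targets had 3 rises and 7 falls among 18 (adjusted p = 0.0968), the circadian clock 4 and 0 among 18 (0.0506), dedifferentiation 4 and 6 among 28 (0.108), immediate early genes 3 and 8 among 28 (0.184), heat shock 0 and 3 among 12 (0.211), the integrated stress response 4 and 4 among 32 (0.501), the unfolded protein response 4 and 3 among 22 (0.501), the interferon response 4 and 1 among 33 (0.474) and p53 targets 3 and 3 among 24 (0.924). Among cell types, cholangiocytes had 1 rise and 2 falls among 13 (0.949), lymphocytes 0 and 1 among 11 (0.924), neutrophils 0 and 0 among 5 (0.924) and erythroid cells 0 and 1 among 5 (0.184). The clock list passed upward under 6 alternatives, from 0.00898 without knockout replicate 4 to 0.0487 without wild type replicate 4. NRF2 targets passed downward without the filter on dim genes (0.0469) and with fry (0.0374), and with fry so did dedifferentiation (2.36e-04), immediate early genes (0.00739), heat shock (0.0356) and erythroid cells (0.00117). Of their brightest members, Cldn4 rose by 1.15 (SE 0.14), Ccl5 fell by 0.77 (SE 0.13) and Tfrc fell by 0.52 (SE 0.11), while Cdh1 (0.31), Ighm (-0.06), Lcn2 (-0.08), Cxcr2 (0.10), Slc4a1 (-0.15), Krt18 (-0.07) and Krt8 (-0.02) did not pass. Median, mean and test differed in sign for the unfolded protein response, p53 targets, immediate early genes, cholangiocytes, lymphocytes and neutrophils.

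How often another grouping of the arrays gives as much was counted over the 35 splits of the 8 arrays into 4 and 4. For changed genes only 1 of the 35 splits, the real one, gave 2119, and the highest of the others gave 0. That share is under 0.05 and is the smallest 35 splits can give; the other splits carry the group difference inside their groups, which lowers their counts. For lists past camera only 1 of the 35 splits, again the real one, gave 26, but the highest of the others gave 24. The 16 splits that keep 3 of the 4 arrays of each group together hold part of the real contrast and gave 10 to 24 lists, while the 18 even splits gave 0 to 4. The count of lists past the test is thus beyond the other splits, but by a narrow margin. The animals' sex is not given. A difference in sex between the groups is argued against: group means of Eif2s3y, Kdm5d, Uty and Xist differed by at most 0.32. None of these genes spread over more than 0.88 across the 8 arrays. Eif2s3y ranged from 7.19 to 8.06, Kdm5d from 5.20 to 6.08 and Uty from 5.10 to 5.93. Xist ranged from 2.59 to 3.03, below the 3.32 used to filter dim genes on every array.

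Hepatocyte genes were higher and endothelial and macrophage markers lower in the knockout. A larger share of hepatocytes as the whole cause would raise hepatocyte genes by a common amount only if all were read on the same scale. The SD of the changes of 19 such genes of middle brightness was 6.43 times their median SE. Compression of dimmer values also spreads the changes, and the SE does not measure it, so this ratio cannot decide the question. A lower share of every other cell type alike cannot be told apart from a loss of some types. Cholangiocyte, lymphocyte, neutrophil and erythroid list means changed by 0.03, -0.05, -0.01 and -0.22, but whether the cultures held these cells was not tested. The changes of the endothelial and stellate list means differed by -0.46 (exact permutation p = 0.0286), but only 6 of the 22 stellate markers had a wild type mean above 5, and these went both ways, from -2.13 for Dcn to 0.99 for Reln. Their changes overlapped those of the 16 endothelial markers above that value (exact rank sum p = 0.641). Fewer endothelial cells and macrophages in the knockout cultures remain a candidate explanation for the marker part: at least 63.6% of the tested markers of both lists fell. Of the 10 brightest, 8 endothelial markers (Cdh5 and Lyve1 lead, at 8.24 and 8.06 in wild type) and 6 macrophage markers fell. Ranked by the mean over all arrays, the 2 brightest macrophage markers, Cd68 and H2-Ab1 (10.9 and 6.74 in wild type), rose instead. Slc40a1, named after its value was seen, was brighter than H2-Ab1 in wild type (7.19) and fell by 0.48. A slower loss of the differentiated state stays open. The dedifferentiation list mean changed by -0.16 (exact permutation p = 0.0286), and fry found its members moving downward (adjusted p = 2.36e-04). Camera did not call the list (adjusted p = 0.108), and of 28 members 4 rose and 6 fell. The change is less than a bound of 0.3, but that bound was set after the results were seen and does not decide the question. The rise of gluconeogenic genes may be part of a rise of hepatocyte genes in general, but the list means cannot decide this. Without shared members they rose by 0.44 for gluconeogenesis and 0.56 for mature hepatocytes (difference -0.12, exact permutation p = 0.0286). Each list pools changed genes with members that did not pass (19 of 36 and 13 of 31 tested), so its mean does not measure the changed genes alone. An effect of p16 loss itself stays open, as does a difference between preparations, which was not tested.

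The 3 tested genes next to Cdkn2a on one side were lower in the knockout, while Cdkn2b and Elavl2 on the other side did not pass the test. Linked sequence acting only on genes within 10 Mb of Cdkn2a could not account for most of the 2119 changes, whatever its effect. Only 60 tested genes lie there, and 2106 of the changes lie farther away or on other chromosomes. This follows from the window's size and is not a test of linked sequence. An excess of changed genes near Cdkn2a is not excluded, with an odds ratio of 1.74 within 10 Mb (Fisher's exact test, p = 0.0888), 1.77 within 20 Mb (p = 0.0105) and 2.07 within 10 Mb without knockout replicate 3 (p = 0.0259). Within 5 Mb the odds ratio was 1.36 (Fisher's exact test, p = 0.579). For the nearest genes an effect of the targeted allele or of linked sequence stays open and was not tested. A variant under the probes of Wincr1 cannot be told apart from a lower level, since the array has 1 row for that gene. Fezf1 and Aass (1.85), neighbours on chromosome 6, both rose, while Cadps2 beside them had a change of -0.28 that did not pass; they were chosen after their values were seen.

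Mcm2 and Mcm3 were lower, and Rrm2 and E2f8 higher, in the knockout. A broad rise of E2F targets, which loss of a CDK4 and CDK6 inhibitor might give, was tested by the mean over the list, which changed by -0.10 (exact permutation p = 0.0571), and by fry, which found its members moving downward (adjusted p = 0.0430), with 9 falls and 2 rises. Camera's downward call was lost with an estimated correlation (adjusted p = 0.416). These values argue against a broad rise in the cultures as measured. A rise within hepatocytes, offset by fewer cell cycle transcripts of other cells, stays open, since endothelial and macrophage list means were lower by 0.83 and 0.59 on the same arrays. What sets Rrm2 and E2f8 apart was not tested.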
